A study of Gallus gallus with 8 samples.

How the data were processed

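Messenger RNA was measured by sequencing in the breast (pectoralis) muscle of 8 broiler chickens, 4 with high and 4 with low shear force. Shear force is the force needed to cut a piece of meat and serves as a measure of its toughness. Per the labels' protocols, the muscle was kept in RNAlater, RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq kit. Each library was sequenced in 2 technical repetitions, per the labels, and the deposited tables hold 1 column per bird. How the repetitions were combined is not given in the sources used here. The shear force of each bird is not used here, because the labels give only its group.

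The authors deposited expected counts, that is, estimated read counts that need not be whole, for 17108 Ensembl genes and 17954 Ensembl transcripts. Of the gene values, 8.22% were not whole numbers. The submitters' processing notes name FastQC, TopHat, Bowtie2, RSEM, Cuffdiff, edgeR and DESeq2, and the genome build galGal4, without versions or the role of each. Filters and strand settings are not given in the sources used here, so overlapping genes on opposite strands may share counts. Per the file headers, a second pair of tables gives the authors' log2 fold changes from edgeR and DESeq2. The sign of these deposited values was tested against the counts and is low over high shear force. It was turned here, so that a positive value means higher in the high shear force birds. The same deposited tables hold the authors' p-values and adjusted p-values from both tools, per the file headers. They cover 8076 genes, all of which were also kept by the filter used here, and 8158 transcripts.

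Gene symbols and coordinates come from the authors' deposited table and are given as written there. Of 10136 genes kept for testing, 7619 had a symbol, 457 had an entry without a symbol, and 2060 had no entry. These 2060 genes entered the tests and counts but could be in no gene list. No reference genome was used here. Some symbols belong to 2 Ensembl genes (LAMC1 and FBN2 among them), and reads may be split between such copies and between close relatives such as the globin genes.

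Counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR 4.0.16 with its defaults, which left 10136 genes with 99.8% of all counts, and 10362 transcripts. Libraries were scaled by TMM factors. The main test was the edgeR quasi-likelihood test with robust dispersion shrinkage, an intercept and the group, and Benjamini-Hochberg adjustment at 0.05, run in R 4.3.3. Every fold change is the high over the low shear force group on the log2 scale, with its SE from that model. CPM values are counts scaled by the TMM library size, given as mean ± SD over 4 birds. All p-values are 2-sided.

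A total of 27 gene lists for this tissue was fixed, of which 26 had 5 or more kept members and were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The nerve and Schwann cell list had 4 kept members and was not tested. Each list was also tested with a correlation estimated from its own members, with fry, and with an exact permutation test of the mean log2 CPM per bird over the 70 assignments of birds, which cannot give a p below 0.0286. Fry's p asks whether the genes of a list move on balance in the same direction, and does not set the list against other genes.

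The design, the test, the gene lists, the rule for named genes and most of the alternative settings were chosen before the data were examined. Under that rule the text names genes with an adjusted p under 0.05, a symbol and a mean log2 CPM of at least 1, and, where fewer than 10 pass, the 10 with the smallest unadjusted p as not passing. It also names up to 4 members with the smallest p of each list with a call, and 11 genes fixed in advance. Of these 11, COL1A1 is not analysed here, because no kept gene carried that symbol. Some genes that the rule names are not reported here. Other genes named were chosen after their values were seen, and the text says so there.

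Alternatives covered RLE and upper-quartile scaling, no filter on low counts, a filter of 1 CPM in at least 4 birds, the replicate number as a block, each bird left out in turn, DESeq2 1.42.0, limma-voom with and without sample quality weights, non-robust shrinkage, a threshold of 0.1, a minimum log2 fold change of 1, and 1 surrogate variable from sva 3.50.0. The edgeR exact test, the edgeR likelihood-ratio test, a fit without low shear force birds 1 and 3, and a list test against named genes alone were added after the data were seen. The replicate numbers were not used to pair birds.

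The procedure was tested on simulated counts for the same birds and the 10136 kept genes, of which 9985 passed the filter again. Of 100 genes changed by 1 on the log2 scale, 46 were recovered, and of 100 changed by 2, 92 were recovered. Among 146 calls 8 were false. On 10362 simulated transcripts, 40 and 94 of 100 were recovered, with 8 false among 142 calls. Each simulated gene was drawn independently of the others, so the simulated birds lack the shared structure of the real libraries. These shares therefore need not hold for the real counts.

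Total expected counts ran from 5564905 to 7322205 per bird. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom was 12.2, between low shear force birds 1 and 3. All 8 were therefore counted as separate birds.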

Results

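The breast muscle of 8 female Hubbard Flex broilers, a commercial meat-type chicken, was profiled at 6 weeks of age. The birds fell into 2 groups of 4 by the shear force of the pectoralis muscle, and the question was which genes differ in level between birds with tougher and with more tender breast meat. Total expected counts were 7057615 ± 317351 (SD, n = 4) in the high and 6474447 ± 718149 (SD, n = 4) in the low shear force birds, which did not differ beyond the spread between birds (exact permutation p = 0.171). Mitochondrial genes took 10.5% ± 1.02 (SD, n = 4) of the counts in the high and 10.97% ± 4.28 (SD, n = 4) in the low shear force birds (exact permutation p = 0.83). The first principal component of log2 CPM, with 32.4% of the variance, did not separate the groups (exact permutation p = 0.314). It set low shear force birds 1 and 3, at 39.0 and 43.9, apart from the other 6 birds, which lay between -24.4 and -3.27.

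**Figure D1:**
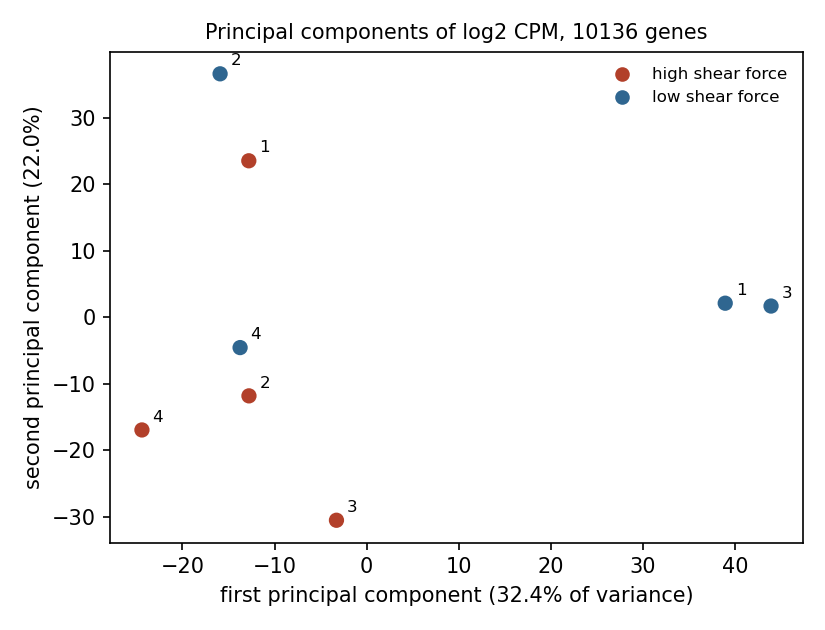
First against second principal component of log2 CPM over 10136 genes, 1 point per bird, numbered by replicate and coloured by group. Low shear force birds 1 and 3 lie at 39.0 and 43.9 on the first component, and the other 6 birds lie at -3.27 or below.

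The fixed lists of extracellular matrix and of collagen maturation genes had the smallest camera p-values of the 26 lists tested, and most of their measured members were more abundant in the high shear force birds. With an estimated correlation neither list was called (adjusted p = 0.282 for both). Among genes with a symbol, those with the smallest p were P4HA3, CPOX, FNDC1 and MFAP5. P4HA3, a subunit of the enzyme that hydroxylates proline in collagen, stood at 18.7 ± 2.41 CPM (SD, n = 4) in the high and 6.995 ± 1.04 CPM (SD, n = 4) in the low shear force birds, a log2 fold change of 1.42 ± 0.19 (SE). MFAP5, a protein of elastic microfibrils, had 368 ± 82.6 CPM (SD, n = 4) against 168 ± 15.9 CPM (SD, n = 4), and FNDC1, a fibronectin-domain protein, 135 ± 22.5 against 67.9 ± 6.63 CPM (SD, n = 4). In the other direction, CPOX, an enzyme of haem synthesis, had 22.2 ± 2.79 CPM in the high and 53.9 ± 13.2 CPM in the low shear force birds (SD, n = 4), a log2 fold change of -1.28 ± 0.19 (SE). None of these differences passed the edgeR quasi-likelihood test over all genes, while DESeq2 called each of them (adjusted p from 4.78e-06 to 6.91e-06).

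By the edgeR quasi-likelihood test 0 of 10136 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.0827, for P4HA3, CPOX and 1 gene without a symbol. An unadjusted p under 0.05 was found for 1301 genes, where 507 would be expected by chance, 803 of them higher and 498 lower in the high shear force birds. At an adjusted p of 0.1 the same test called 5 genes, 4 higher and 1 lower. Other tools on the same counts called more: DESeq2 called 113 genes (80 higher, 33 lower), the edgeR exact test 126 (100 higher, 26 lower), the edgeR likelihood-ratio test 135 and limma-voom with sample quality weights 24, while limma-voom without weights called 0. In 626 genes (6.18%) all 4 birds of one group lay above all 4 of the other, where chance gives 2.86%. The number of genes with an unadjusted p under 0.05 fell to 799 without low shear force bird 1, to 822 without low shear force bird 3 and to 787 without both. The balance of directions also depended on single birds: without low shear force bird 2 it reversed, to 743 higher and 832 lower. Without low shear force bird 4 it narrowed to 1015 higher and 902 lower. With each other bird left out in turn, more genes were higher than lower.

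The 10 genes with a symbol and the smallest p had no overlap between the groups, and 8 of them were higher in the high shear force birds. Genes picked by a small p tend to show no overlap, so this adds little. The adjusted p-values of these 10 ran from 0.0827 to 0.107 (edgeR), so that each failed the threshold. P4HA3 lies on chromosome 1 at 194915190 to 194923866 and CPOX on chromosome 1 at 83561890 to 83573845, in the coordinates of the authors' deposited table. FNDC1 (chromosome 3, 45071689 to 45111718) had a log2 fold change of 0.99 ± 0.16 (SE), and MFAP5 (chromosome 1, 75420699 to 75436042) one of 1.13 ± 0.18 (SE). SPON2, a secreted matrix protein of the spondin family (chromosome 4, 84441720 to 84468575), stood at 1.501 ± 0.27 (SE). EFEMP1, a fibulin of the extracellular matrix, stood at 0.88 ± 0.16 (SE), and SERPINF1, a secreted serpin, at 0.82 ± 0.15 (SE). THRSP, a regulator of fatty acid synthesis, had the largest difference of the 10, at 2.01 ± 0.34 (SE), from low levels of 7.51 ± 2.75 CPM against 1.85 ± 0.267 CPM (SD, n = 4). ZNF385D, a zinc finger protein, stood at 1.06 ± 0.18 (SE).

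**Figure D2:**
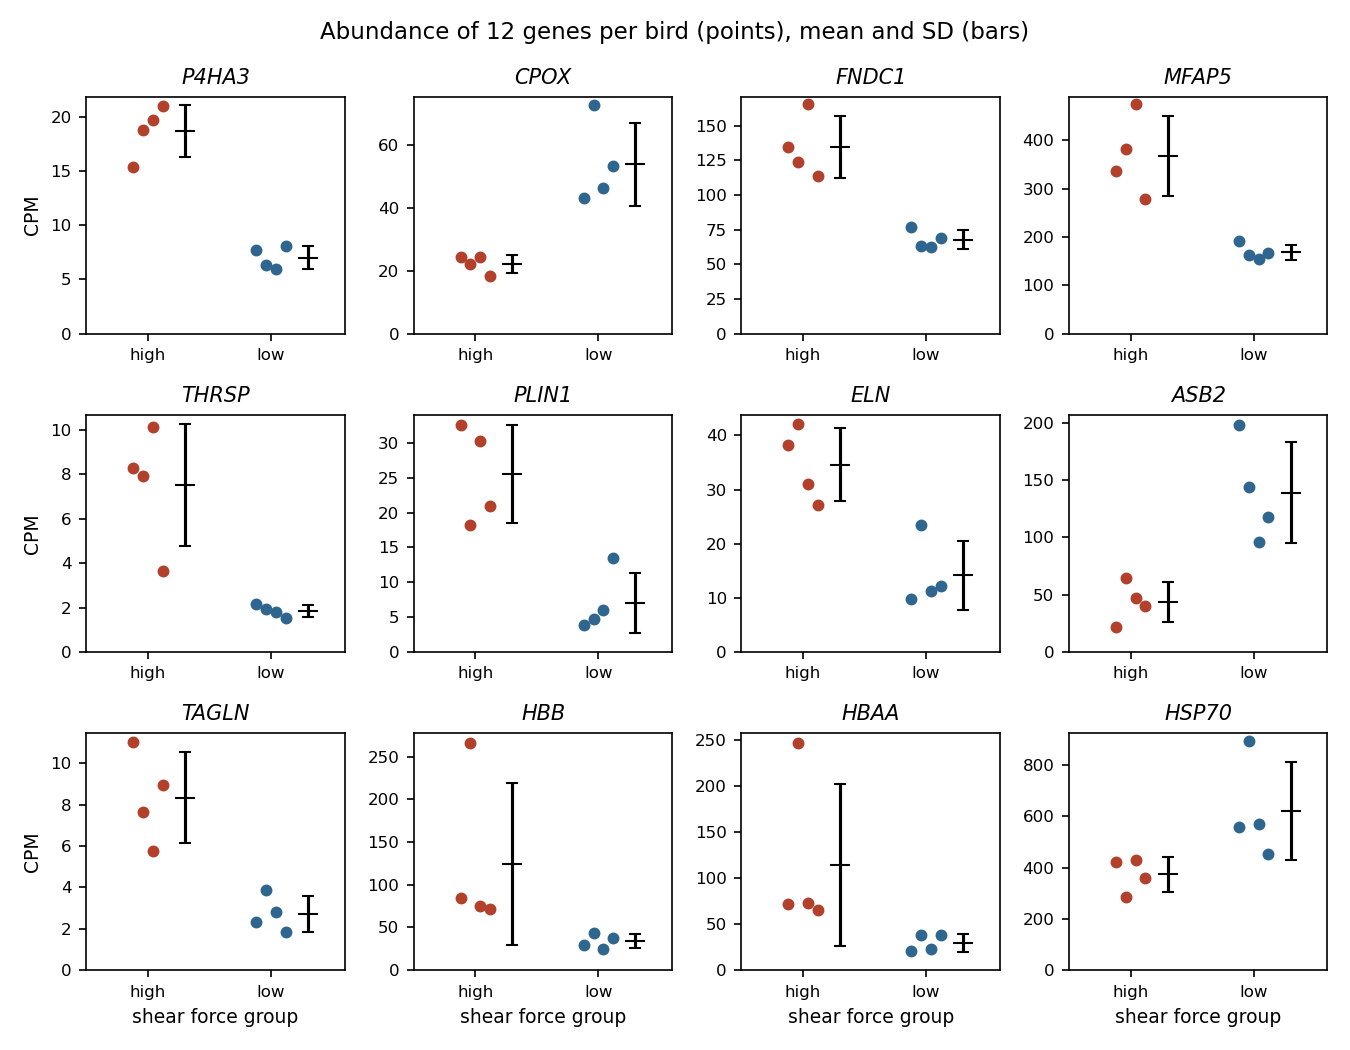
CPM of 12 genes in each bird (points, linear axes from 0), with the mean and SD of each group of 4 beside them. The 4 high shear force birds lie above the 4 low shear force birds for P4HA3, FNDC1, MFAP5, THRSP, PLIN1, ELN, TAGLN, HBB and HBAA, and below them for CPOX, ASB2 and HSP70.

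Most structural genes of the extracellular matrix were higher in the high shear force birds: 32 of 35 measured members had a positive log2 fold change, with a median of 0.48. ELN, which encodes elastin, had 34.6 ± 6.77 CPM against 14.2 ± 6.32 CPM (SD, n = 4), a log2 fold change of 1.30 ± 0.27 (SE). The chains of collagen VI that lie around muscle fibres, COL6A1 and COL6A2, stood at 0.63 ± 0.17 and 0.57 ± 0.17 (SE), OGN, a small proteoglycan, at 0.63 ± 0.14 (SE), and POSTN, a matricellular protein, at 0.54 ± 0.16 (SE). TNC, tenascin C, went the other way, at -0.68 ± 0.21 (SE). COL3A1, fixed in advance, stood at 0.56 ± 0.39 (SE) with an edgeR adjusted p of 0.562 and did not pass; its value ran from 0.27 to 0.86 with 1 bird left out, and was 1.41 ± 0.33 (SE) without low shear force birds 1 and 3. The list was called by camera (adjusted p = 2.26e-08), but not with an estimated correlation (adjusted p = 0.282). Over all genes none of the 35 passed by edgeR quasi-likelihood, while DESeq2 called 4, all higher. Adjusted over the list alone, 9 passed in edgeR, 8 higher and TNC lower. COL6A2, TNC, COL8A1, COL1A2 and COL5A2, of these 9, lie outside the rule for named genes and were chosen after their values were seen. The count of 9 fell to 0 without high shear force bird 2, low shear force bird 1 or low shear force bird 3, to 2 without high shear force bird 3, and to 1 without low shear force birds 1 and 3 together, where the median was 0.51. With 1 bird left out the median ran from 0.34 to 0.55. Camera with its preset correlation called the list each time, at a largest adjusted p of 1.08e-05 without low shear force bird 2.

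Genes for collagen maturation and cross-linking were likewise higher, 16 of 18 measured members, with a median log2 fold change of 0.56. Besides P4HA3, these were led by PCOLCE2, an enhancer of procollagen processing, at 1.22 ± 0.25 (SE), FKBP10, a collagen chaperone, at 0.91 ± 0.24 (SE), and LOXL3, a lysyl oxidase of the family that starts collagen and elastin cross-links, at 0.86 ± 0.24 (SE). LOX itself stood at 0.58 ± 0.19 (SE). PLOD2, which hydroxylates lysine in collagen ends, did not differ beyond the spread between birds, at -0.20 ± 0.13 (SE) with an edgeR adjusted p of 0.552. The list was called by camera (adjusted p = 9.21e-07) and by fry (adjusted p = 0.0203), but not with an estimated correlation (adjusted p = 0.282). Over all genes 0 members passed by edgeR, and 9 passed adjusted over the list alone, all of them higher. FKBP10 was at 0.59 without low shear force birds 1 and 3. The count of 9 fell to 2 without high shear force bird 3 or low shear force bird 3, to 4 without low shear force bird 1, to 5 without low shear force bird 2, and to 2 without low shear force birds 1 and 3 together. With 1 bird left out the median ran from 0.43 to 0.62. Camera with its preset correlation called the list each time, at a largest adjusted p of 2.0e-05 without high shear force bird 3.

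Matrix proteases and their inhibitors were higher in 15 of 17 members, with a median of 0.36 (camera adjusted p = 0.000522; adjusted p = 0.282 with an estimated correlation). The gelatinase MMP2 stood at 0.60 ± 0.14 (SE) and its inhibitor TIMP2 at 0.75 ± 0.18 (SE). MMP17, a membrane-anchored protease, stood at 0.73 ± 0.23 (SE) and SERPINE2 at 0.40 ± 0.13 (SE). By the edgeR quasi-likelihood test none passed over all genes, where DESeq2 called 2, each higher. In edgeR 6 passed adjusted over the list alone, 5 higher and ADAMTS20 lower, the last chosen after its value was seen.

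**Figure D3:**
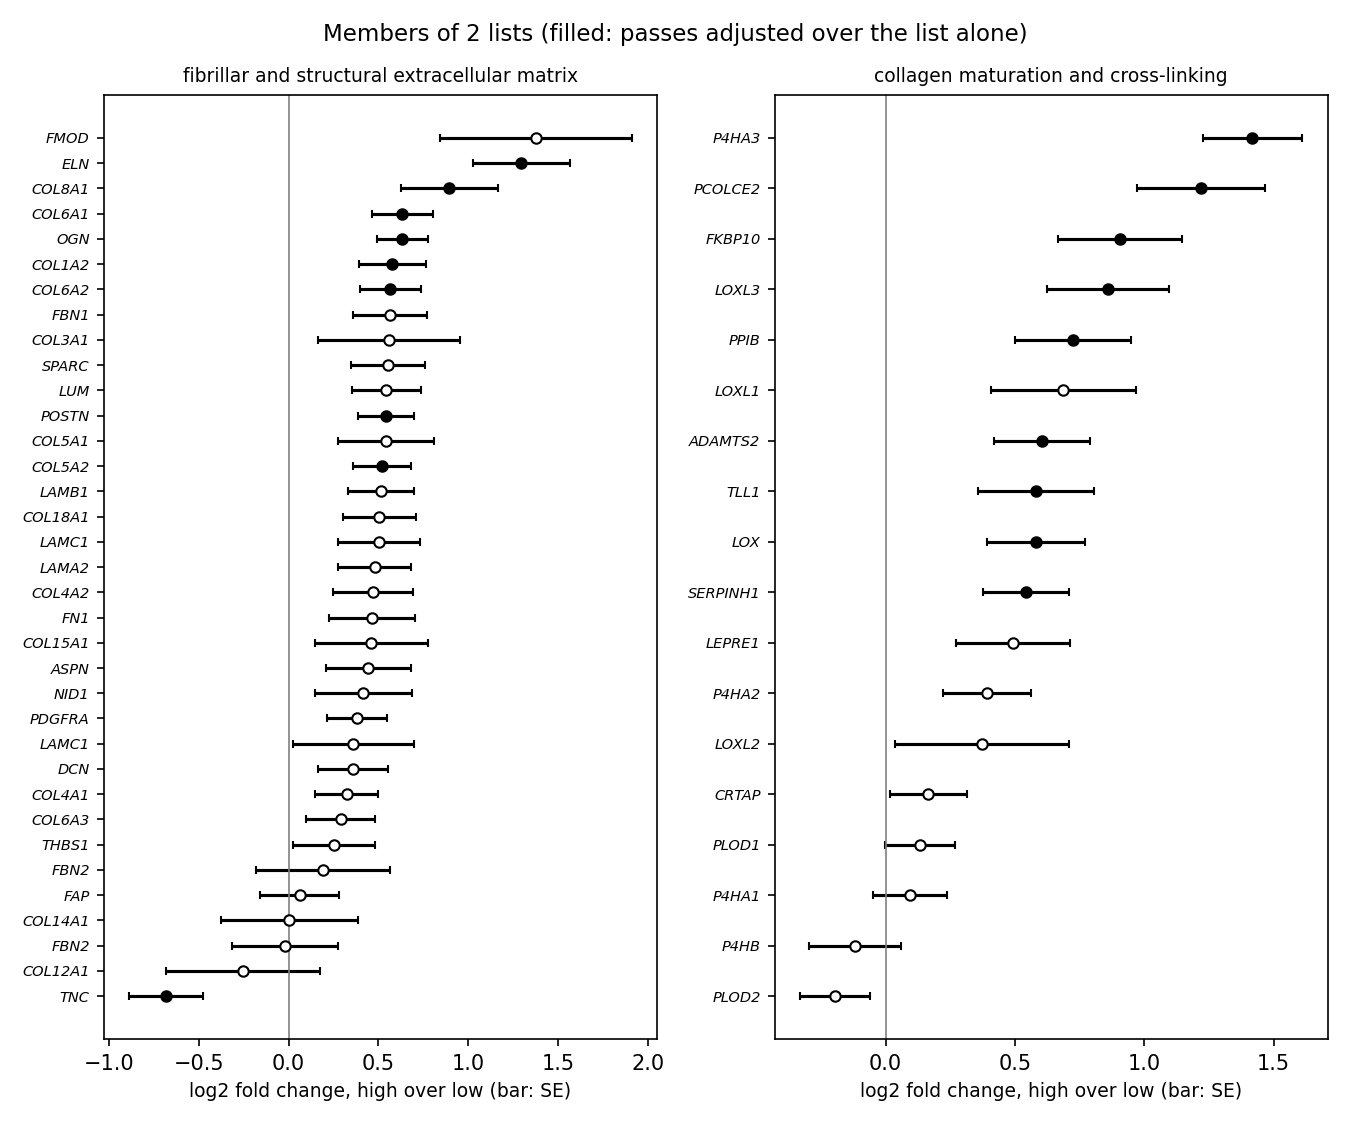
Log2 fold change, high over low shear force, of each measured member of the matrix list (35 members) and of the collagen maturation list (18 members), with its SE as a bar. Filled points pass adjusted over the list alone, 9 in each list, and a symbol printed more than once belongs to more than 1 Ensembl gene.

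Most measured markers of vessels, fat cells and red blood cells were also higher in the high shear force birds. None passed over all genes by the edgeR quasi-likelihood test, and their lists were called by camera only with its preset correlation. DESeq2 called 0 endothelial, 2 smooth muscle, 2 adipocyte and 3 erythrocyte genes, all higher. All 16 endothelial genes measured had a positive log2 fold change, with a median of 0.48, led by PLVAP at 1.14 ± 0.32 and ENG at 0.84 ± 0.28 (SE), with TIE1 and TEK at 0.70 ± 0.29 and 0.47 ± 0.21 (SE). Of 15 genes of smooth muscle and pericytes, the cells around vessels, 11 were higher, with a median of 0.57: TAGLN stood at 1.61 ± 0.30, RGS5 at 0.85 ± 0.26, MYLK at 0.82 ± 0.19 and MYH11 at 0.57 ± 0.17 (SE). Of 22 genes of adipocytes and lipid synthesis 16 were higher, with a median of 0.28. PLIN1, which coats lipid droplets, stood at 25.5 ± 7.01 CPM against 7.02 ± 4.38 CPM (SD, n = 4), a log2 fold change of 1.87 ± 0.36 (SE). FABP4, a fatty acid carrier of fat cells, stood at 0.50 ± 0.33 (SE) with an edgeR adjusted p of 0.532, ELOVL5 at 0.54 ± 0.21 (SE) and LPIN1 at -0.59 ± 0.20 (SE). Of 9 erythrocyte genes 6 were higher and 3 lower, with a median of 0.42. The haemoglobin genes HBB, HBAA and HBAD were 3.69-fold, 3.85-fold and 4.51-fold higher, while CA2, which red cells share with other tissues, stood at 0.67 ± 0.36 (SE). The globin values leaned on high shear force bird 2, without which the log2 fold changes were 1.19, 1.24 and 1.23 in place of 1.88, 1.94 and 2.17. With 1 bird left out FABP4 ran from 0.25 to 0.84 and CA2 from 0.21 to 0.92. Without low shear force birds 1 and 3 PLVAP was at 0.64, TIE1 at 0.43, TEK at 0.30, ELOVL5 at 0.20 and FABP4 at 0.28.

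These calls came from camera with its preset correlation, at adjusted p-values of 0.000326 for endothelium, 0.00374 for smooth muscle and pericytes, 0.0211 for adipocytes and 0.0323 for the 9 erythrocyte genes. With an estimated correlation the adjusted p-values were 0.444, 0.282, 0.343 and 0.343. Over all genes 0 members passed by edgeR, and adjusted over the list alone 0, 5, 2 and 3 passed, all higher. Without high shear force bird 3 the medians fell to 0.31 for endothelium and 0.27 for smooth muscle and pericytes, both still called (endothelium was at 0.29, also called, without low shear force birds 1 and 3), and without low shear force bird 2 to 0.17 for adipocytes and 0.25 for erythrocytes, neither of them called. The adipocyte call also ended without high shear force bird 1 or 2, and the erythrocyte call without high shear force bird 1 or low shear force bird 4, while the adipocyte median was 0.46 without low shear force bird 4. Leukocyte and macrophage genes were not called (median 0.18, camera adjusted p = 0.595), with 17 of 25 higher, but were called without high shear force bird 1 (median 0.29, adjusted p = 0.00913). Their median was -0.04 without high shear force bird 3, 0.10 without high shear force bird 4, 0.04 without low shear force bird 2, and -0.02 over all 8 birds once the trend with genomic span was removed. Among 4 nerve and Schwann cell genes measured, the median was -0.11.

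In 3 lists of muscle protein turnover and stress most members were lower in the high shear force birds, but only camera with its preset correlation called these lists, and the exact permutation p-values of the mean per bird were 0.114 for atrophy, 0.114 for heat shock and 0.0571 for autophagy. Of 25 genes of muscle atrophy and ubiquitin ligases 19 were lower, with a median of -0.29 (camera adjusted p = 0.00319; adjusted p = 0.444 with an estimated correlation). ASB2, a substrate adaptor of a muscle ubiquitin ligase, had 43.4 ± 17.6 CPM against 139 ± 44.1 CPM (SD, n = 4), a log2 fold change of -1.68 ± 0.31 (SE), and was the single member that passed adjusted over the list alone. ASB14 stood at -0.57 ± 0.25, USP14 at -0.33 ± 0.15 and KLF15 at -0.84 ± 0.40 (SE). Of 40 heat shock and unfolded protein genes 27 were lower, with a median of -0.11 (camera adjusted p = 0.00627; adjusted p = 0.282 with an estimated correlation). The chaperones HSP70 and HSPA8 stood at -0.73 ± 0.22 and -0.51 ± 0.16, HSPH1 at -0.72 ± 0.23 and HSPA4L at -0.53 ± 0.18 (SE), and 0 passed adjusted over the list alone. Of 29 autophagy and lysosome genes 22 were lower, with a median of -0.11 (camera adjusted p = 0.0465; adjusted p = 0.343 with an estimated correlation) and none that passed adjusted over the list alone. LAMP2 stood at -0.41 ± 0.20, UVRAG at -0.49 ± 0.26, NBR1 at -0.38 ± 0.19 and ATG4A at -0.31 ± 0.17 (SE). The first 3 of these leaned on low shear force birds 1 and 3, without which they were at -0.18, -0.042 and -0.036, while ATG4A was at -0.49, ASB14 at -0.21 and KLF15 at -0.54. The atrophy median was -0.17 without low shear force bird 2, and the heat shock call ended without that bird (adjusted p = 0.0623), with a median of -0.20 without high shear force bird 1. The autophagy call ended with upper-quartile scaling and without high shear force bird 2, 3 or 4 or low shear force bird 2 (adjusted p from 0.0607 to 0.198), and its median was -0.17 without low shear force bird 3.

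Cell cycle genes were higher in 22 of 27 cases, with a median of 0.31 (camera adjusted p = 0.00319; adjusted p = 0.505 with an estimated correlation). CDC2 stood at 0.81 ± 0.26, CKAP2 at 0.78 ± 0.26, CDCA8 at 0.64 ± 0.20 and MCM2 at 0.61 ± 0.21 (SE), and 0 passed adjusted over the list alone. Without low shear force bird 2 the median was 0.14 and the list was not called (adjusted p = 0.127), and without low shear force birds 1 and 3 CDC2 was at 0.50 and CDCA8 at 0.34. Nuclear genes of oxidative phosphorylation were higher in 46 of 54 cases by a small amount, with a median of 0.18 (camera adjusted p = 0.0169; adjusted p = 0.843 with an estimated correlation). UQCRH stood at 0.58 ± 0.22, NDUFC2 at 0.52 ± 0.20, ATP5D at 0.44 ± 0.20 and ATP5S at -0.64 ± 0.28 (SE), and 0 passed adjusted over the list alone. Without low shear force birds 1 and 3 UQCRH, NDUFC2 and ATP5D were at 0.25, 0.28 and 0.14. The median turned to -0.10 without these 2 birds, with a camera adjusted p of 0.0350, and was 0.05 over all 8 birds once the trend of fold change with genomic span was removed. The call also ended without high shear force bird 1, 2 or 4 or low shear force bird 1 or 3, at medians of 0.16, 0.10, 0.16, 0.07 and 0.09, and the median was 0.28 without low shear force bird 2.

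**Figure D4:**
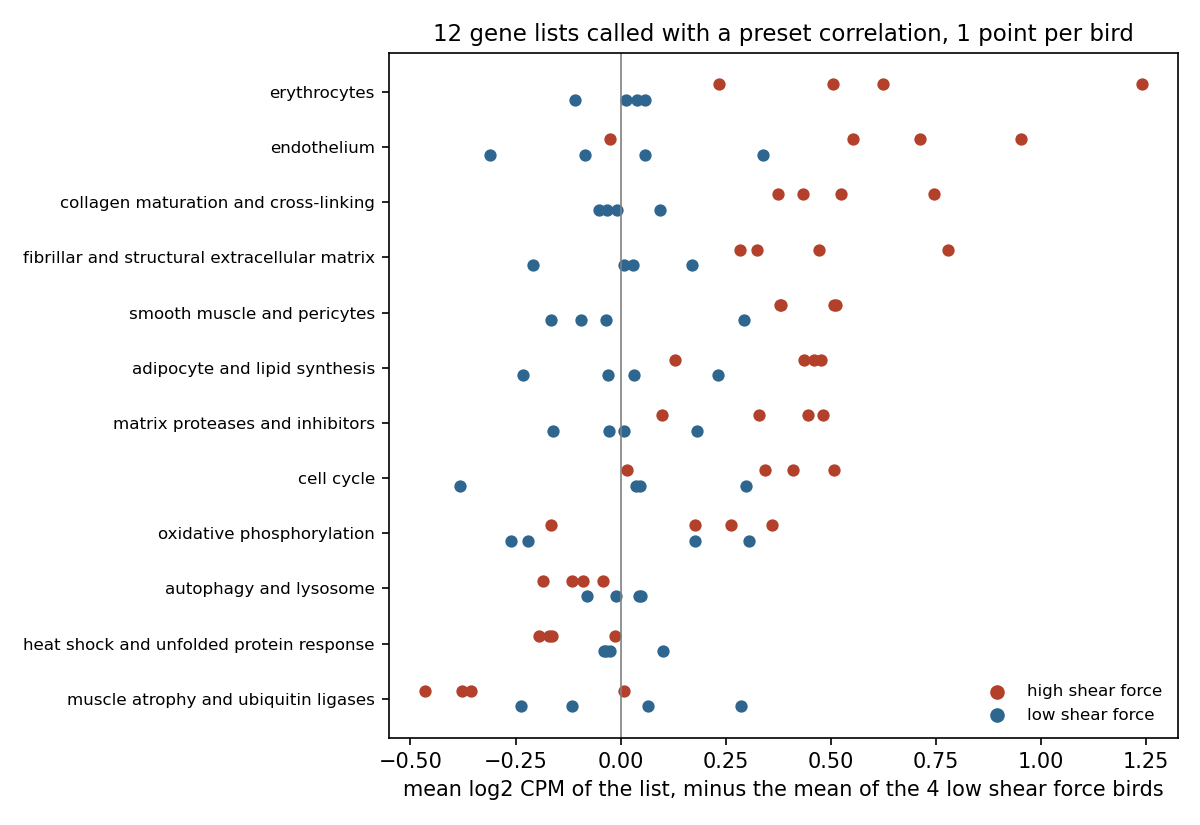
Mean log2 CPM of the 12 lists called by camera with its preset correlation in each bird, relative to the mean of the 4 low shear force birds, 1 point per bird. The 4 high shear force birds lie above the 4 low shear force birds for the matrix, collagen maturation, smooth muscle and erythrocyte lists, and the groups overlap for the other 8.

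In all, 12 of 26 lists were called by camera, 0 with an estimated correlation, 1 by fry and 0 by the exact permutation test of the mean per bird after adjustment (smallest adjusted p 0.186). The permutation test could hardly call a list after adjustment. Its unadjusted p cannot fall below 0.0286, so that many of the 26 lists would have to stand at that value together. Without low shear force bird 2 the number called by camera was 7.

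Genes for the enzymes that act on meat after slaughter did not differ beyond the spread between birds. CAPN1 and CAPN2, calcium-activated proteases, stood at -0.21 ± 0.14 and 0.26 ± 0.29 (SE), CAPN3 at -0.54 ± 0.25 (SE), and CAST, which encodes their inhibitor calpastatin, at -0.25 ± 0.23 (SE). Their unadjusted p-values in edgeR were 0.156, 0.398, 0.0546 and 0.305. With 1 bird left out CAPN2 ran from -0.02 (without high shear force bird 3) to 0.43, CAPN3 from -0.75 to -0.28 and CAST from -0.42 to -0.11, and without low shear force birds 1 and 3 CAPN3 was at -0.21 and CAST at 0.19. The list of calpains, calpastatin and cathepsins was not called (camera adjusted p = 0.638), and its median of 0.02 differed in sign from its mean of -0.05 and its camera direction. PRKAG3, a muscle subunit of the AMP-activated kinase, stood at 0.21 ± 0.20 (SE) with an edgeR adjusted p of 0.683, and ran from 0.04 to 0.32 with 1 bird left out.

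Other lists of muscle fibre and energy genes, apart from oxidative phosphorylation, were not called by camera in the main test. Camera adjusted p-values were 0.0631 for calcium handling (median -0.16), 0.0901 for slow, embryonic and cardiac muscle genes (median -0.17), 0.197 for fast skeletal muscle genes (median -0.13) and 0.192 for myogenesis and satellite cells (median 0.12). They were 0.105 for fatty acid oxidation (median -0.12), 0.129 for glycogen and AMPK (median -0.15) and 0.912 for glycolysis (median 0.01). The myogenesis median ran from 0.02 to 0.21 with 1 bird left out, and was -0.005 once the trend with genomic span was removed. Over all 8 birds, calcium handling was called with no filter on low counts, and calcium handling and slow muscle with the replicate number as a block. Calls also appeared with birds left out: for the calcium, slow muscle, fast muscle, fatty acid oxidation and glycogen lists without high shear force bird 1 (medians -0.25, -0.26, -0.16, -0.24 and -0.28), for calcium handling without high shear force bird 3 (-0.24), for the calcium, fast muscle and glycogen lists without low shear force bird 4 (-0.31, -0.29 and -0.24), for slow muscle and fatty acid oxidation without low shear force bird 3 (-0.15 and -0.13), and for fatty acid oxidation without low shear force birds 1 and 3 together (-0.20). Other birds left out weakened these lists: without low shear force bird 1 the medians were -0.03 for slow muscle, -0.06 for fast muscle and -0.09 for calcium handling, which was at -0.10 without low shear force bird 3, glycogen was at -0.09 without high shear force bird 2 and fatty acid oxidation at -0.07 without high shear force bird 4. Without low shear force birds 1 and 3 together calcium handling turned to 0.12 and fast muscle to 0.02, and slow muscle and glycogen were at -0.04 and -0.06. For signalling and stress lists they were 0.638 for the circadian clock (median -0.05), 0.682 for the interferon response (median 0.09) and 0.912 for immediate early genes (median 0.01). The hypoxia list (adjusted p = 0.912) had a median of -0.01 and a mean of 0.003. The list of steroid, thyroid and insulin signalling (adjusted p = 0.699) had a median of -0.11 and a mean of 0.04, and camera gave both lists a negative direction. Adjusted over the list alone, 2 myogenesis genes and THRSP in the hormone list were higher, 1 slow muscle gene was lower and 1 nerve gene was higher. Over all genes 0 passed by edgeR quasi-likelihood, and DESeq2 called 2, 1, 1 and 0 members of these lists in that order. The myogenesis genes were FST, a myostatin antagonist, at 0.98 ± 0.18, and IGFBP4 at 1.18 ± 0.26 (SE). The slow muscle gene was the myosin heavy chain MYH15 at -1.38 ± 0.29 (SE), and the nerve gene was PMP22 at 0.61 ± 0.17 (SE). These 4 were chosen after their values were seen.

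Among transcripts with a name, the 3 with the smallest p were those of the 3 leading genes. P4HA3-201 stood at 1.42 ± 0.19 (SE), CPOX-201 at -1.27 ± 0.19 (SE) and FNDC1-201 at 0.99 ± 0.15 (SE). By the edgeR quasi-likelihood test 0 of 10362 transcripts had an adjusted p under 0.05 (smallest 0.108), 1285 had an unadjusted p under 0.05 (785 higher, 500 lower), and DESeq2 called 131 (89 higher, 42 lower).

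The authors' deposited table called more genes than the present quasi-likelihood fit. In the authors' deposited table, edgeR called 91 genes, 66 higher and 25 lower in the high shear force birds, DESeq2 called 147, and both tools called the same 85, 63 higher and 22 lower. The log2 fold changes for CPOX, SPON2, ASB2 and P4HA3 in the authors' deposited table, turned to high over low, were -1.30, 1.48, -1.70 and 1.40 from edgeR. Across the 8076 genes in the authors' deposited table, the edgeR log2 fold changes and those from the present fit had a correlation of -0.99999 in the deposited orientation, over genes, which are not independent replicates. All 85 genes called by both tools in the authors' deposited table had an unadjusted p under 0.05 in the present fit, 81 had no overlap between the groups, and their adjusted p-values here ran from 0.0827 to 0.258 (edgeR). These genes were called from the same birds, so their small p-values and lack of overlap here are not independent evidence. The present quasi-likelihood fit called 0 genes and so shared 0 calls with the authors' deposited table, while the present DESeq2 fit shared 84. The authors' deposited table gave 94 transcripts called by edgeR, 152 by DESeq2 and 90 by both.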

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

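Of the tests in this part, the 35 splits with DESeq2 and the edgeR exact test and the principal component without mitochondrial genes were set before their results were seen, as were the camera and exact permutation tests of the fixed lists, and every other test was chosen only after its result was seen. In 192 groups of 4 birds, over library measures, list means and named genes, 11 held a bird far from the other 3, and chance alone gives about 9.6.

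HBB, HBAA and HBAD were each highest in high shear force bird 2, at 266, 246 and 98.4 CPM, while the next bird of that group had 84.5, 73.1 and 21.7 CPM, and the gap took 0.936, 0.956 and 0.979 of the range of the group. High shear force bird 1 had the highest mitochondrial share of its group, 12.03% against 10.1% for the next (0.875 of the range). High shear force bird 4 had the lowest mean of the adipocyte list, 4.63 against 4.94 log2 CPM (0.887), and the lowest LOX, 62.1 against 84.1 CPM (0.844). Low shear force bird 2 had the highest mean of the heat shock list, 6.39 against 6.26 log2 CPM (0.908), the highest PCOLCE2, 28.6 against 16.5 CPM (0.870), and the lowest SERPINF1, 340.3 against 357 CPM (0.920). CDC2 was highest in low shear force bird 4, at 13.6 against 6.84 CPM (0.959), and ATP5S in high shear force bird 3, at 6.52 against 4.47 CPM (0.848).

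Chance is not excluded for the counts of genes and lists above 0. For the 0 genes and 0 transcripts called by the edgeR quasi-likelihood test the 35 splits of the 8 birds into 4 and 4 decide nothing, since any split gives at least 0 (35 of 35 for each), and the highest other splits gave 1 gene and 4 transcripts. The 1301 genes with an unadjusted p under 0.05 were matched or exceeded in 4 of 35 splits, the real one included, with 1993 in the highest other. DESeq2 called 113 genes in the real split and as many or more in 3 of 35, with 559 in the highest other, and the edgeR exact test called 126, likewise reached in 3 of 35, with 461 in the highest other. The highest other split, which set high shear force bird 1 with low shear force birds 1, 2 and 3, called several times the real count with DESeq2, which points to a structure of the samples. It leaves 6 of the 8 birds with their group, so that part of its calls may be the group difference itself, which was not tested. A split with high shear force birds 1 and 4 beside low shear force birds 2 and 4 balances the groups. The group difference cannot raise its calls, yet DESeq2 called 174 genes, the exact test 263, and 1368 had an unadjusted p under 0.05. A structure of the samples apart from the groups can thus give counts above the real ones. The other balanced splits called at most 85 genes with DESeq2. The 12 lists called by camera were matched or exceeded in 9 of 35 splits, with 16 in the highest other.

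The higher level of matrix genes in the high shear force birds was set against 4 explanations. Chance stays open: 1 of 35 splits, the real one, gave a median of 0.48, and the highest other gave 0.38, but this list was singled out as the strongest of 26. Its exact permutation p, the smallest that the permutations can give, was 0.186 after adjustment over the 26. That adjusted p could pass only if many lists stood at the same smallest p, so it decides little. Its camera p of 8.69e-10 was reached in 2 of 35 splits, the real one included, with 2.10e-12 in the other. The trend of the fold change with genomic span, as fitted on the 8076 genes with a position, does not carry it, as the median was 0.560 after this trend was removed over the 35 members, all with a position. A larger share of 1 unchanged cell type would raise the members alike only if that cell type alone made all of them. The members differed by more than their errors, with TNC lower: Cochran's Q over the 35 genes, treated as independent, was 64.2, which chance exceeds with a probability of 0.00130. This argues against that simple form only. A larger share of a cell type that makes some members more than others stays open. A lower share of muscle fibre stays open, because the mean difference per bird of the matrix genes exceeded that of the leukocyte genes by 0.35 with an exact permutation p of 0.143, as does a difference that goes with shear force itself, which was not tested apart from these.

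Low shear force birds 1 and 3 lie apart from the other 6 on the first principal component, by a gap of 42.2. The counts of mitochondrial genes themselves do not make this gap, as it was 42.5 without those genes. These 2 birds had the lowest mitochondrial shares, 8.45% and 6.30%, against 9.87% to 15.2% in the other 6. Leaving those genes out cannot tell whether the gap shares a cause with the lower mitochondrial share. Across the 8076 genes with a position, the log2 ratio of these 2 birds over low shear force birds 2 and 4 had a Spearman correlation of 0.427 with genomic span. Birds 1 and 3 alone gave 0.391 and 0.410, which over these genes met the rule chosen for a dependence on gene length. The group fold change had a correlation of -0.32 with span. Only 79.7% of the kept genes had a position, under the 80% required here, so that the check does not decide for all kept genes. A dependence on gene length between the libraries may therefore be involved and cannot be told apart from other causes in these tables. No biological explanation was tested, since no group in the labels separates these 2 birds.

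More red blood cells in the sampled muscle are a candidate explanation for the higher globin genes. The 3 genes kept nearly 1 ratio across the 8 birds, with a largest SD of the log2 ratio of 2 globins of 0.303, while their mean level had an SD of 1.14. Of the 9 erythrocyte genes measured 6 were higher and 3 lower, and only the 3 globins had an unadjusted p under 0.05 in edgeR. The other members of that list therefore give this explanation little backing. A difference in sequencing depth between the groups is divided out by the scaling, so that a check of it could hardly turn out otherwise. The total expected counts before scaling had a log2 ratio of 0.1244 for high over low, against 1.88 or more for the 3 genes. Whether blood left in the muscle or more blood in it gives this was not tested, and reads shared between related globin genes may also tie their levels.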

How the results depend on the processing

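The edgeR likelihood-ratio and exact tests, the fit without low shear force birds 1 and 3, and the list test against named genes alone were chosen after seeing the data. The 0 genes called by the edgeR quasi-likelihood test, with 1301 at an unadjusted p under 0.05, stayed 0 with RLE and upper-quartile scaling, a filter of 1 CPM, non-robust shrinkage, a minimum fold and limma-voom. The count was 113 with DESeq2, 126 with the exact test, 135 with the likelihood-ratio test, 24 with sample quality weights, 12 with 1 surrogate variable, 7 with no filter and 5 at an adjusted p of 0.1. It ran from 0 to 7 with 1 bird left out, highest without low shear force bird 2. Transcripts called numbered 131 with DESeq2 and 0 to 3 with 1 bird left out. Genes with an unadjusted p under 0.05 numbered 2151 with sample quality weights, 787 without low shear force birds 1 and 3, and 799 to 1917 with 1 bird left out. Calls shared with the authors' deposited table were 5 at an adjusted p of 0.1 and 84 with DESeq2. Lists called numbered 0 with an estimated correlation, 1 with fry, 0 with the permutation test, 14 with the replicate block, 13 with no filter, 13 without low shear force birds 1 and 3, 11 with upper-quartile scaling, 11 against named genes alone and 7 to 15 with 1 bird left out, against 12 in the main test.

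Matrix members passing adjusted over the list alone, 9 in the main test, numbered 14 with DESeq2, 14 with the exact test, 14 with the likelihood-ratio test, 15 with sample quality weights, 28 with 1 surrogate variable, 1 without low shear force birds 1 and 3, and 0 to 11 with 1 bird left out. For collagen maturation the numbers were 2 without those 2 birds and 2 to 12 with 1 bird left out.

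Whether the replicate numbers pair the birds is not known, as the labels do not say. Deviations of birds with the same number correlated at 0.014, -0.0032, 0.21 and 0.32, and only the birds numbered 4 matched each other best, which is too little to decide. With the replicate block 1 gene was called and 15 matrix members passed. The hypoxia median was 0.017 and that of immediate early genes -0.011 with the block.

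Several medians changed sign, most of them near 0, and the cause was not tested. With RLE scaling they were -0.011 for calpains, -0.018 for glycolysis and -0.014 for immediate early genes, and with upper-quartile scaling 0.0039 for hypoxia. With no filter glycolysis was at -0.0054. With the 1 CPM filter calpains were at -0.0029, glycolysis at -0.0093 and immediate early genes at -0.0040. Without low shear force birds 1 and 3 the medians were -0.10 for oxidative phosphorylation (0.18 over all birds, and called both times), 0.12 for calcium handling (-0.16 over all birds), 0.023 for fast muscle genes (-0.13 over all birds), -0.011 for calpains, 0.014 for the circadian clock, 0.045 for hypoxia, -0.11 for immediate early genes and 0.017 for hormone signalling, and CAST was at 0.19. With 1 bird left out medians ran from -0.094 to 0.097 for calpains, -0.13 to 0.014 for the circadian clock, -0.033 to 0.080 for glycolysis, -0.035 to 0.072 for hypoxia, -0.16 to 0.071 for immediate early genes, -0.11 to 0.27 for the interferon response, -0.041 to 0.29 for leukocytes and -0.29 to 0.050 for hormone signalling, and CAPN2 from -0.019 to 0.43. RLE scaling split the unadjusted calls into 700 higher and 593 lower, against 803 and 498. The technical runs apart were not run, because the tables hold 1 column per bird. Depth was within 5564905 to 7322205 counts in every bird. In the simulation, where genes were drawn independently, 46 of 100 changes of 1 on the log2 scale were recovered.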

Other observations

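Of the tests in this part, those of sterol synthesis and the proteasome were set before their results were seen, and that of elastic fibre genes was chosen only after members of it had been seen in the fixed lists. All 3 lists were drawn up after the data were seen, and the genes that raised each question, with every gene that stands in a fixed list, were left out of its test.

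Genes of cholesterol synthesis tended to be more abundant in the high shear force birds. LSS and SC4MOL, enzymes of that pathway chosen after their values were seen, stood at 1.14 ± 0.23 and 0.98 ± 0.24 (SE), with edgeR adjusted p-values of 0.118 and 0.181, and of 16 other measured members of the pathway 13 were higher, with a median log2 fold change of 0.39. SQLE stood at 0.82 ± 0.28, CYP51A1 at 0.77 ± 0.23, HSD17B7 at 0.75 ± 0.25 and DHCR7 at 0.63 ± 0.22 (SE), while HMGCS1, which acts early in the pathway, stood at -0.22 ± 0.22 (SE). None passed adjusted over the list alone, and 6 had an unadjusted p under 0.05 in edgeR. The mean per bird was higher by 0.36, with an exact permutation p of 0.0571 (adjusted 0.0857), which misses the threshold, so that a group change remains a hypothesis. Camera gave an adjusted p of 0.000782 over these 3 lists, and 0.104 with an estimated correlation.

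Elastic fibre genes may be higher as a group, beyond ELN, MFAP5, EFEMP1 and EMILIN2, which were left out. Of 8 other members that stand in no fixed list 6 were higher, with a median of 0.51. By the edgeR quasi-likelihood test 4 passed adjusted over the list alone, and none over all genes. MFAP2 stood at 0.99 ± 0.26, FBLN5 at 0.87 ± 0.32, FBLN1 at 0.76 ± 0.22 and LTBP1 at 0.65 ± 0.20 (SE), while MFAP3 and ADAMTSL3 stood at -0.17 ± 0.17 and -0.06 ± 0.31 (SE). The mean per bird was higher by 0.42, with an exact permutation p of 0.0286, the smallest the permutations can give (adjusted 0.0857, which misses the threshold). The values of these 8 genes come from the same birds as the fixed matrix and collagen lists, so that this is not independent of them.

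The proteasome gave a negative result. PSMD12, chosen after its value was seen, belongs to 2 Ensembl genes, which stood at -0.98 ± 0.26 and -0.01 ± 0.16 (SE), and HSPA8 stood at -0.51 ± 0.16 (SE). The mean of 33 other proteasome genes per bird differed by -0.05 with an exact permutation p of 0.657 (adjusted 0.657), and 10 of the 33 were higher and the rest lower. The single member with an unadjusted p under 0.05 in edgeR, PSMD1, was lower, at -0.40 ± 0.15 (SE).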
